A study of Arabidopsis thaliana with 12 samples.

How the data were processed

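Transcript levels were measured on 12 Affymetrix ATH1 arrays, which probe most Arabidopsis genes known when the array was designed with sets of short oligonucleotides. Each array held RNA from excised seeds of the WS accession. Per the labels, the seeds came from 2 genotypes, named WT and KD, at 3 stages: 14 and 16 days after flowering (14DAF and 16DAF) and the dry seed collected after desiccation. There were 2 arrays for each genotype and stage. Flowers had been marked, seeds were dissected out of the siliques of the marked age, and total RNA was treated with DNase and labelled by a repeated amplification protocol. The labels do not spell out KD. The series describes a genotype of altered lysine metabolism and cites work by Zhu and Galili, which joined a knockout of LKR/SDH, the first enzyme of lysine catabolism, to a bacterial dihydrodipicolinate synthase expressed in seeds. The sources used here do not say which of these changes the KD seeds carried.

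The deposited values are on a log2 scale, as inferred from their range, and were made with RMA, with Partek also named, per the submitters' processing notes. Versions and settings, and whether the 12 arrays were normalized together, are not given in the sources used here. RMA corrects the background, aligns the arrays' distributions and summarises the probes of a set, so a shift of all transcripts in one direction would be hidden by it. The deposited log2 values were used without further normalization. No per-sample column was left unused, no array was left out, and the number of arrays limits the precision. No detection calls were used, so a log2 difference against a dim signal has an uncertain size.

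The groups came from the sample titles. For WT 16DAF replicate 1 and KD dry replicate 1 the source name gave the other genotype than the title, the description and the genotype label, and the title was followed. Nothing in the labels says that the 2 repeats of a group were separate plants or harvests, so p-values measure only the spread between these samples, which may be technical.

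Of 22810 probe sets, 64 controls were removed and 22746 were tested. The platform annotation gave 1 gene for 13513 probe sets (59.4%) and several for 503, and it listed none for 8730, which are unnamed here. Locus codes were matched to the gene table of the TAIR10.1 assembly for 13436 of the probe sets with 1 gene, and symbols were taken from that table. For 11933 of them the name is the locus code alone. The named probe sets covered 13350 genes.

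Linear models were fitted with limma 3.58.1 in R 4.3.3 to 6 group means over all 12 arrays, with moderated variances (eBayes without trend, 6 residual and 4.16 prior degrees of freedom). For each of 10 contrasts the p-values were adjusted by Benjamini-Hochberg over all probe sets, and the threshold was an adjusted p of 0.05. All tests were two-sided. The contrasts were the stage changes within each genotype, the KD minus WT difference at each stage, its average over the stages, and the interaction of genotype with each stage step. Errors beside log2 differences are standard errors of this model, and errors beside group levels are SDs of 2 arrays. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

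The contrasts, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. LKR/SDH was read first in every array. For each contrast the rule took the 10 largest increases and the 10 largest decreases among probe sets past the threshold that named 1 gene. The ranges of the compared arrays had to be free of overlap; the average over stages needed the same sign at all 3 stages, and the interactions had no such condition. From each gene list, up to 4 members with the largest absolute change could be named as well. The text reports part of these genes. Changes called largest are the largest among probe sets that met this rule, since unnamed probe sets were not ranked.

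The 17 gene lists covered late embryogenesis abundant (LEA) proteins, seed storage proteins, oil body proteins, fatty acid and oil synthesis, reserve mobilisation, sucrose and raffinose, seed regulators, photosynthesis, the TCA cycle, amino acid catabolism, the aspartate family of amino acids, heat shock, ER folding and DNA replication, with markers of the other tissues that an excised seed sample could hold: seed coat, endosperm, and silique wall with funiculus. They held 331 loci, of which 76 had a probe set naming them alone, and none of the sucrose and raffinose loci did (0 measured). The 8 lists with at least 3 measured members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over these lists in each contrast; the correlation was also estimated, and fry was run. A planned list of ribosomal proteins, selected by description, matched 0 probe sets. After the data had been seen, 4 lists were added by locus (cytosolic ribosomal proteins, ribosome biogenesis, and the genes of the plastid and mitochondrial genomes), and their p-values were adjusted over all lists. For a gene with several probe sets, the brightest was used in the lists. The list called amino acid catabolism in the text was drawn up for amino acid catabolism and low energy together.

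The alternatives were arrays centred on their medians, quantile normalization, only probe sets above log2 5 on at least 2 arrays, eBayes with a trend or robust, array weights, the replicate number as a block, an added minimum of a 2-fold change, only the arrays a contrast compares, leaving out the arrays with conflicting source names, and leaving out each array in turn. An array left alone in its group was assumed to vary like the other groups. Centring and quantile normalization of the list tests were added after the data had been seen. The procedure was tested on simulated data for KD against WT at 14DAF over 22746 probe sets. It recovered 51% of 100 changes of log2 1 and 93% of 100 changes of log2 2, with 3 false among 147 calls. The simulated noise was independent between probe sets and arrays, so this does not give the share of false calls in the real data.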

Results

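The 12 arrays profiled seeds of the WT and KD genotypes at 14DAF, 16DAF and in the dry state, with 2 arrays per genotype and stage. These stages take the seed from reserve accumulation through the end of maturation into desiccation. Replicate arrays correlated at r = 0.983 (WT 16DAF) to 0.993 across probe sets, and each array correlated best with the other array of its own group. The first principal component held 74.7% of the variance and followed the stage; the second held 9.2%. Between 48.9% and 52.9% of the probe sets of an array lay above log2 5. The median signal of the dry groups was lower than that of the 16DAF groups, at 4.95 against 5.16 in WT and 4.92 against 5.10 in KD. The 3' minus 5' signal of the control transcripts, a measure of RNA integrity and labelling, averaged 3.11 ± 0.08, 2.95 ± 0.64 and 2.19 ± 0.26 in WT at 14DAF, 16DAF and in dry seeds, and 2.89 ± 0.55, 2.41 ± 0.22 and 2.21 ± 0.21 in KD (SD, n = 2).

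LKR/SDH (AT4G33150), which encodes the first enzyme of lysine catabolism, was higher in every KD array than in every WT array. Its log2 signal in WT was 10.36 ± 0.09 at 14DAF, 10.21 ± 0.57 at 16DAF and 9.01 ± 0.20 in dry seeds (SD, n = 2). In KD it was 13.60 ± 0.40, 13.19 ± 0.25 and 12.82 ± 0.02. The arrays ranged from 8.87 to 10.61 in WT and from 12.8 to 13.88 in KD. WT 16DAF replicate 1 (9.8) and KD dry replicate 1 (12.83), whose source names give the other genotype, lay with the genotype of their titles. Where the probe set lies relative to any insertion is not given in the sources used here, so the higher signal checks no knockout.

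**Figure D1:**
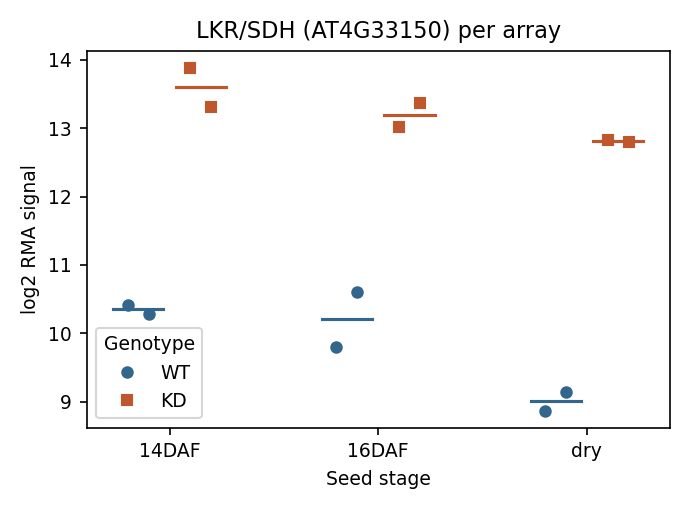
Log2 RMA signal of LKR/SDH (y axis) at the 3 seed stages (x axis), with 1 point per array, blue circles for WT and orange squares for KD, and a line at each group mean. The KD arrays lie between 12.8 and 13.88 and the WT arrays between 8.87 and 10.61.

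The first comparison asked which transcripts changed in WT seeds between 14DAF and 16DAF. LEA genes, whose products accumulate as seeds acquire desiccation tolerance, were among the largest increases. AT3G53040 rose 23.9-fold, from 7.57 ± 0.57 to 12.15 ± 0.45 (SD, n = 2; log2 change 4.58, SE 0.269, adjusted p = 1.62e-05). AT2G42560 rose by 3.84 (SE 0.309) and LEA4-5 by 3.46 (SE 0.302). Of 20 measured LEA genes, 13 rose and 0 fell, with the same counts adjusted over the list alone; the median change was 1.18 (camera adjusted p = 1.09e-06, and adjusted p = 0.203 with an estimated correlation). The small heat shock genes AT1G53540 (2.2, SE 0.425) and AT2G29500 (1.32, SE 0.277) passed as well, but not from the arrays of this contrast alone (adjusted p = 0.057 and 0.0619). Of the 4 measured heat shock genes, 3 rose, also adjusted over the list alone (camera adjusted p = 0.0156, and adjusted p = 0.328 with an estimated correlation).

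Photosynthesis genes fell over the same days in WT. Phosphoribulokinase (PRK), an enzyme of the Calvin cycle, fell by 3.96 (SE 0.451, adjusted p = 0.000258), as did PSBY (-2.66, SE 0.243) and the ATP synthase gene ATPC1 (-2.55, SE 0.414). Of 10 measured photosynthesis genes, 6 fell and 0 rose, or 7 and 0 adjusted over the list alone (median -2.27, camera adjusted p = 1.09e-06, and adjusted p = 0.236 with an estimated correlation). Geranylgeranyl reductase (AT1G74470), which supplies the side chain of chlorophyll, fell 25.02-fold, from 9.03 ± 1.22 to 4.38 ± 0.07 (SD, n = 2). Its end level lay below the medians of the WT 16DAF arrays (5.11 and 5.2), so the size of this fall is uncertain. In amino acid catabolism 5 of 7 genes fell and 0 rose, also adjusted over the list alone, among them the methylcrotonyl-CoA carboxylase subunit MCCB (-1.73, SE 0.275) and ETFALPHA (-1.07, SE 0.172); the median was -0.76 (camera adjusted p = 0.000184, and adjusted p = 0.203 with an estimated correlation), and 3 passed without WT 16DAF replicate 2. The aspartate family (0 of 5 passing, camera adjusted p = 0.723), the TCA cycle (1 of 8 up and 2 down, also adjusted over the list alone, adjusted p = 0.293) and the storage proteins (0 of 5 up and 1 down, 2 down adjusted over the list alone, adjusted p = 0.343) did not move as lists. Storage proteins had a median of 0.015 and a mean of -0.248.

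Among genes outside the lists, AT1G17010 rose most in WT (5.21, SE 0.227, adjusted p = 2.42e-06), followed by AT2G39210 (5.21, SE 0.173). The GDSL lipase gene AT1G71691 fell by 4.61 (SE 0.325) and DELTA-VPE, a vacuolar processing enzyme of the seed coat, fell by 4.04 (SE 0.456). BAN, which makes tannin precursors in the seed coat, fell by 2.91 (SE 0.424, adjusted p = 0.00105). It was the only one of 3 seed coat markers to pass, with 2 passing adjusted over the list alone. The list's camera adjusted p was 0.0562, and it was 0.0237 without WT 14DAF replicate 1, 0.031 without either KD 14DAF array and 0.0391 with the arrays centred. The DNA replication gene PRL measured -0.55 (adjusted p = 0.094), and -0.88 without WT 14DAF replicate 1 (adjusted p = 0.0106). In all, 2092 probe sets rose and 2337 fell. That total of 4429 was 2219 without WT 14DAF replicate 2. With the arrays centred on their medians, 59% of the calls were increases, against 47.2% as deposited.

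From 16DAF to the dry seed, M17, another LEA gene, showed the largest increase among named genes in WT. It rose 347-fold, from 5.05 ± 1.51 to 13.49 ± 0.77 (SD, n = 2; log2 change 8.44, SE 1.15, adjusted p = 0.000221). The start level lay near the medians of the WT 16DAF arrays (5.11 and 5.2) and varied between them, so the fold is uncertain. M10 rose by 5.26 (SE 1.06), AT3G22490 by 4.25 (SE 0.487) and the dehydrin LTI30 by 3.12 (SE 0.325). Of 20 LEA genes, 12 rose and 2 fell, or 13 and 2 adjusted over the list alone (median 0.81, camera adjusted p = 0.00153, and adjusted p = 0.436 with an estimated correlation). All 4 measured heat shock genes rose, also adjusted over the list alone, led by AT1G53540 (4.89, SE 0.425) and AT2G29500 (3.32, SE 0.277); the median was 2.85 (camera adjusted p = 0.00153, and adjusted p = 0.436 with an estimated correlation). The 3' minus 5' control signal was lower in the dry WT arrays, at 2.19 ± 0.26 against 2.95 ± 0.64 at 16DAF.

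Genes of oil synthesis and oil bodies were too few for a list test, with 2 of 33 and 2 of 8 measured. The acyl-ACP thioesterase gene FaTA fell by 3.97 (SE 0.167, adjusted p = 1.49e-07) and FATB fell by 1.4 (SE 0.195), in drying WT seeds. Of the oil body genes, OLEO3, an oleosin, fell by 2.44 (SE 0.255) and AT3G01570 fell by 0.68 (SE 0.156, adjusted p = 0.00611, and 0.0502 without WT dry replicate 2). Isocitrate lyase (ICL), an enzyme of the glyoxylate cycle, rose by 1.73 (SE 0.16) and the lipase gene SDP1 by 1.49 (SE 0.201), both of the measured genes of reserve mobilisation. The ER chaperone gene CRT1b fell by 2.96 (SE 0.308), as did the seed coat gene DFR (-1.96, SE 0.231) and the bZIP regulators EEL (-2.18, SE 0.142) and BZIP53 (-1.29, SE 0.278). Storage protein genes AT1G03890 (-1.66, SE 0.214) and AT4G36700 (-1.18, SE 0.141) fell, with 3 of 5 down and 1 up, also adjusted over the list alone (camera adjusted p = 0.128). MCCB (2.41, SE 0.275) and MCCA (1.36, SE 0.166) rose. In amino acid catabolism 3 of 7 genes rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.0844). The TCA cycle genes went both ways, 2 up and 2 down, or 3 and 3 adjusted over the list alone (median -0.09, mean 0.064, camera adjusted p = 0.736), with IDH-V at 1.23 (SE 0.191) and SDH2-1 at -1.18 (SE 0.16). In the aspartate family 1 of 5 rose and 2 fell (camera adjusted p = 0.203), with the methionine gamma-lyase gene MGL at -1.87 (SE 0.185).

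In drying WT seeds AT5G55620 fell strongly (-8.27, SE 0.393, adjusted p = 2.66e-07), from 12.49 ± 0.52 to 4.23 ± 0.19, as did AT1G62500 (-8.17, SE 0.455), from 11.79 ± 0.71 to 3.62 ± 0.45 (SD, n = 2). The end levels lay near the lower quartiles of the WT dry arrays (3.7 and 3.74) and were not shown to be above background, so the sizes of these decreases are uncertain. AT2G34740 rose by 6.69 (SE 0.614) and AT5G17540 by 5.41 (SE 0.158). Among photosynthesis genes 1 of 10 rose and 3 fell, or 1 and 4 adjusted over the list alone (camera adjusted p = 0.128, and 0.0353 with the arrays centred), with PSAE-1 at -2.42 (SE 0.348) and PSBY at -1.69 (SE 0.243). Over all probe sets 4633 rose and 3843 fell (8476 in all). Increases were 54.7% of these calls as deposited and 70.5% with the arrays centred, since the dry arrays have lower medians.

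In KD seeds the step from 14DAF to 16DAF again raised LEA genes. AT3G22490 rose 10.7-fold, from 4.49 ± 0.26 to 7.91 ± 0.95 (SD, n = 2; log2 change 3.43, SE 0.487, adjusted p = 0.00353), LTI30 by 2.81 (SE 0.325) and AT3G53040 by 1.75 (SE 0.269). Of 20 LEA genes, 6 rose and 1 fell, or 12 and 1 adjusted over the list alone (median 0.60, camera adjusted p = 7.19e-06, and adjusted p = 0.497 with an estimated correlation). Those rising numbered 3 without KD 14DAF replicate 1 or KD 16DAF replicate 2, and 10 without either WT 16DAF array. Of 10 photosynthesis genes, 2 fell and 0 rose, or 3 and 0 adjusted over the list alone (median -0.87, camera adjusted p = 0.0274, and adjusted p = 0.502 with an estimated correlation). That list's adjusted p was 0.196 without KD 14DAF replicate 1 and 0.0845 without KD 16DAF replicate 1, and 0 of its genes passed without either of these or KD 16DAF replicate 2. PRK measured -1.90 (SE 0.451, adjusted p = 0.0282), with adjusted p = 0.187 without KD 14DAF replicate 1, 0.108 without KD 16DAF replicate 1 and 0.126 without KD 16DAF replicate 2. Heat shock genes had a median of 0.64, with 0 of 4 passing over all probe sets or adjusted over the list alone (camera adjusted p = 0.181, and 0.042 without either WT 16DAF array and 0.0481 without the arrays of conflicting source names). Amino acid catabolism (0 of 7 up and 1 down, or 1 and 3 adjusted over the list alone, camera adjusted p = 0.189) and the TCA cycle (1 of 8 up and 0 down, or 2 and 0 adjusted over the list alone, camera adjusted p = 0.189) did not pass.

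AT1G17010, the gene that rose most in WT over these days, also led in KD (3.83, SE 0.227, adjusted p = 0.000205), and the sugar transporter gene SWEET6 rose by 2.76 (SE 0.296). AT4G13840 fell by 2.97 (SE 0.297), as did ATL8, a RING-type ubiquitin ligase gene (-2.82, SE 0.315), and AT2G23360 (-2.34, SE 0.176, adjusted p = 0.000541). In KD 1054 probe sets rose and 1106 fell. The total of 2160 depended on single arrays: it was 430 without KD 14DAF replicate 1, 1343 without KD 14DAF replicate 2, 1067 without KD 16DAF replicate 1 and 503 without KD 16DAF replicate 2. Centring moved the share of increases from 48.8% to 67.4%. Across probe sets the changes in the genotypes correlated (r = 0.703, rho = 0.541), with 669 shared increases against 96.9 for independent lists and 758 shared decreases against 113.6.

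Drying of KD seeds moved many of the genes that moved in WT. M17 rose 201-fold, from 5.79 ± 2.33 to 13.44 ± 0.74 (SD, n = 2; log2 change 7.65, SE 1.15, adjusted p = 0.00044), M10 by 5.25 (SE 1.06) and AT3G22490 by 3.46 (SE 0.487). The start level of M17 varied widely between the 2 arrays here too, so its fold is uncertain. Of 20 LEA genes, 14 rose and 1 fell, or 14 and 2 adjusted over the list alone (median 1.03, camera adjusted p = 0.00033, and adjusted p = 0.361 with an estimated correlation). Heat shock genes AT1G53540 (3.35, SE 0.425), AT2G29500 (2.92, SE 0.277) and AT5G37670 (2.11, SE 0.388) rose, 3 of 4 also adjusted over the list alone (median 2.51, camera adjusted p = 0.0152, and adjusted p = 0.361 with an estimated correlation). The genes of branched-chain amino acid breakdown MCCB (3.30, SE 0.275), IVD (2.21, SE 0.258) and MCCA (1.91, SE 0.166) rose. In that list 4 of 7 rose and 0 fell, also adjusted over the list alone (median 0.63, camera adjusted p = 0.0165, and adjusted p = 0.361 with an estimated correlation). The TCA cycle had 3 of 8 up and 0 down, with a median of -0.03 and a mean of 0.226 (camera adjusted p = 0.699).

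FaTA fell by 4.17 (SE 0.167) and OLEO3 fell by 3.26 (SE 0.255) in drying KD seeds, while ICL (1.75, SE 0.16) and SDP1 (1.74, SE 0.201) rose. AT3G01570 measured -0.46 (adjusted p = 0.0451), with adjusted p = 0.06 without either WT 14DAF array, 0.0572 without either WT dry array, 0.1 and 0.181 without KD 16DAF replicates 1 and 2, 0.292 without KD dry replicate 1, 0.27 without the arrays of conflicting source names (log2 change -0.30), 0.0658 from the arrays of this contrast alone and 0.188 with the arrays centred. PSBY fell by 2.25 (SE 0.243) and sedoheptulose-bisphosphatase (SBPASE) fell by 1.72 (SE 0.217). Photosynthesis genes (0 of 10 up and 4 down, also adjusted over the list alone) had a camera adjusted p of 0.0526, which was 0.041 without either WT 14DAF array, 0.0345 without either KD 14DAF array, 0.033 without KD 16DAF replicate 1, 0.0302 without KD dry replicate 1, 0.0314 without the arrays of conflicting source names, 0.0148 with the arrays centred and 0.0421 after quantile normalization. Storage proteins (2 of 5 down, also adjusted over the list alone) had 0.0526 as well, which was 0.0345 without either KD 14DAF array, 0.033 without KD 16DAF replicate 1, 0.0156 without KD dry replicate 2, 0.0366 with the arrays centred and 0.0216 after quantile normalization. EEL fell by 1.67 (SE 0.142) and DFR fell by 1.91 (SE 0.231). The glucosyltransferase gene UGT76E12 rose by 5.59 (SE 0.380, adjusted p = 2.46e-06), the expansin gene EXPA15 fell by 6.44 (SE 0.444) and AT2G34700 fell by 7.76 (SE 0.341). In all, 4457 probe sets rose and 3487 fell (7944 in all). Increases made up 56.1% of these calls, or 70% with the arrays centred. The change from 16DAF to dry correlated between the genotypes at r = 0.899 (rho = 0.798), with 3331 shared increases against 907.8 for independent lists and 2724 shared decreases against 589.1.

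KD and WT were compared at each stage. At 14DAF, some LEA genes were higher in KD. AT3G53040 stood at 11.10 ± 0.01 in KD and 7.57 ± 0.57 in WT (SD, n = 2), 11.6-fold higher (log2 difference 3.54, SE 0.269, adjusted p = 0.000348), and AT2G42560 (3.06, SE 0.309) and LEA4-5 (3.01, SE 0.302) were higher too. Of 20 LEA genes, 3 were higher and 0 lower, or 6 and 0 adjusted over the list alone (median 0.49, camera adjusted p = 0.000397, and adjusted p = 0.333 with an estimated correlation), and 5 were higher without WT 14DAF replicate 1. Of 10 photosynthesis genes, 2 were lower in KD and 0 higher, or 5 and 0 adjusted over the list alone (median -1.01, camera adjusted p = 0.000397, and adjusted p = 0.333 with an estimated correlation). Without WT 14DAF replicate 2 the photosynthesis median was -0.24 (adjusted p = 0.116). Its lower genes numbered 8 without WT 14DAF replicate 1, 0 without WT or KD 14DAF replicate 2, and 1 without KD 14DAF replicate 1, any dry array or either KD 16DAF array. SBPASE measured -0.99 (SE 0.217, adjusted p = 0.0242), with adjusted p = 0.161 without WT 14DAF replicate 2, 0.0603 without KD 14DAF replicate 1, 0.161 without KD 14DAF replicate 2 and 0.0906 from the arrays of this contrast alone. Markers of other tissues did not pass at this stage: ALC of the silique wall measured -0.22 (adjusted p = 0.319) and AGL62 of the endosperm 0.24 (adjusted p = 0.511). ADPG1 of the silique measured 2.21 (SE 0.942, adjusted p = 0.206), which was 0.0422 without either WT 16DAF array, and BAN -1.17 (adjusted p = 0.135), which was -1.88 without WT 14DAF replicate 1 (adjusted p = 0.0149). Seed coat markers had 0 of 3 passing (camera adjusted p = 0.509).

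LKR/SDH was 9.45-fold higher in KD at 14DAF (log2 difference 3.24, SE 0.267, adjusted p = 4e-04). It was the 1 member of 5 in the aspartate family to pass, with 2 adjusted over the list alone. The list, which holds LKR/SDH, was not tested without it at any stage. The list had a median of 0.14 and a mean of 0.836 (camera adjusted p = 0.0403, and adjusted p = 0.333 with an estimated correlation). That call was lost without WT 14DAF replicate 1 (adjusted p = 0.177) or KD 14DAF replicate 1 (0.058), and 2 members passed without WT 14DAF replicate 2 or either WT 16DAF array. Amino acid catabolism had 1 of 7 lower, or 2 adjusted over the list alone (median -0.31, camera adjusted p = 0.0403, and adjusted p = 0.333 with an estimated correlation), lost without WT 14DAF replicate 2 (0.252) or KD 14DAF replicate 1 (0.158) and after quantile normalization (0.0953). In it 0 passed without WT 14DAF replicate 2, any KD array or the arrays of conflicting source names, and 2 without either WT 16DAF array. The TCA cycle (0 of 8, or 2 up adjusted over the list alone) had a median of -0.20 and a mean of 0.024 (camera adjusted p = 0.989), and heat shock genes had 0 of 4 passing (camera adjusted p = 0.509). Among named genes AT1G73490 showed the largest difference, 19.5-fold higher in KD (4.29, SE 0.203, adjusted p = 2.27e-05). AT1G68670, a MYB-family regulator, measured 2.78 (SE 0.228) and the ribosomal protein gene AT2G32220 2.49 (SE 0.337). AT5G64550 (-2.35, SE 0.26) and AT1G53070 (-2.06, SE 0.290) were lower. At 14DAF 763 probe sets were higher and 891 lower in KD, and the total of 1654 was 473 without WT 14DAF replicate 2, 1007 without KD 14DAF replicate 1 and 441 without KD 14DAF replicate 2. After quantile normalization 56.7% of the calls were higher in KD, and 55.2% with the arrays centred, against 46.1% as deposited, so here too the majority direction depended on the scaling.

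**Figure D2:**
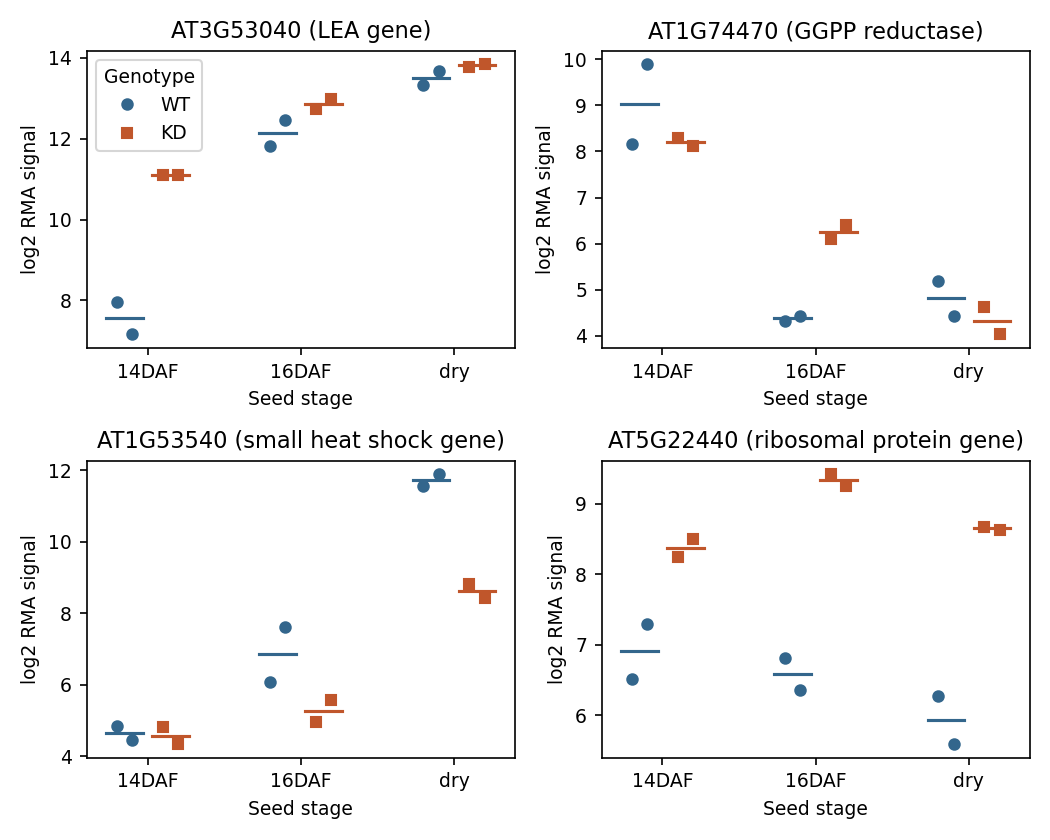
Log2 RMA signal (y axes) of a LEA gene, a chlorophyll side chain gene, a small heat shock gene and a ribosomal protein gene at the 3 seed stages (x axes), with 1 point per array, blue circles for WT, orange squares for KD and a line at each group mean. AT3G53040 differs most at 14DAF (log2 difference 3.54) and AT1G53540 in dry seeds (-3.12).

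At 16DAF some genes of the aspartate family and the TCA cycle were higher in KD. AT1G14810, aspartate semialdehyde dehydrogenase of the lysine, threonine and methionine pathway, was 3.0-fold higher in KD, at 9.15 ± 0.21 against 7.57 ± 0.22 (SD, n = 2; log2 difference 1.59, SE 0.232, adjusted p = 0.00232). LKR/SDH (AT4G33150) was 7.92-fold higher (2.99, SE 0.267). In the aspartate family 3 of 5 were higher and 0 lower, or 3 and 1 adjusted over the list alone. The median was 0.56 and the mean, with LKR/SDH in the list, 0.94 (camera adjusted p = 0.0319, and adjusted p = 0.208 with an estimated correlation). The TCA cycle genes SDH2-1, a succinate dehydrogenase subunit (1.12, SE 0.16, adjusted p = 0.00216), and AT2G20420 (1.05, SE 0.155) were higher. That list had 2 of 8 higher and 0 lower, or 2 and 1 adjusted over the list alone (median 0.29, camera adjusted p = 0.0405, and adjusted p = 0.272 with an estimated correlation). Its adjusted p was 0.0578 without either WT 14DAF array, 0.163 without WT 16DAF replicate 1, 0.192 without KD 16DAF replicate 2 and 0.149 without the arrays of conflicting source names. Of 4 heat shock genes 1 passed as lower in KD, or 2 adjusted over the list alone (median -0.86, camera adjusted p = 0.0405, and adjusted p = 0.474 with an estimated correlation), and the call of the list was lost without WT 16DAF replicate 2 (0.226) or KD 16DAF replicate 1 (0.104). The gene that passed, AT1G53540, measured -1.58 (SE 0.425, adjusted p = 0.0391), with adjusted p = 0.146 without WT 16DAF replicate 2 (log2 difference -0.81), 0.216 and 0.0745 without KD 16DAF replicates 1 and 2, 0.0553 without either WT dry array, 0.0567 without either KD dry array and 0.177 from the arrays of this contrast alone. Without each of these 7 arrays 0 of 4 passed, and 3 did without WT 16DAF replicate 1 or the arrays of conflicting source names. The 3' minus 5' control signal was 2.41 ± 0.22 in KD and 2.95 ± 0.64 in WT.

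The small heat shock gene AT1G54050, which is outside that list, was 9.1-fold lower in KD (-3.19, SE 0.541, adjusted p = 0.00479), with an adjusted p of 0.0518 from the arrays of this contrast alone. LEA genes had 2 of 20 higher and 1 lower, also adjusted over the list alone (camera adjusted p = 0.405, and 0.0471 without WT 16DAF replicate 2). Photosynthesis genes had 1 of 10 higher and 0 lower (camera adjusted p = 0.244), and amino acid catabolism 1 of 7 (0.244). Storage proteins had 0 of 5 passing, or 1 higher adjusted over the list alone, with a median of -0.14 and a mean of 0.129 (camera adjusted p = 0.81). AT1G17960 was 20.4-fold higher in KD (4.35, SE 0.388, adjusted p = 0.000277), AT1G71691 14.1-fold (3.82, SE 0.325), and the ribosomal protein genes AT5G22440 (2.75, SE 0.284) and AT3G28900 (2.44, SE 0.283) were higher as well. AT1G27030 was lower (-3.30, SE 0.251, adjusted p = 0.000127), as was XTH16, a xyloglucan endotransglucosylase gene (-2.37, SE 0.306). In total 1188 probe sets were higher and 1337 lower. Those higher made up 47% of the calls as deposited, 55.9% with the arrays centred and 52.7% after quantile normalization, so the majority direction depended on the scaling. The sum of 2525 was 1514 without KD 16DAF replicate 1 and 1019 without KD 16DAF replicate 2.

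In dry seeds the heat shock genes were lower in KD. AT1G53540 stood at 8.62 ± 0.28 in KD and 11.73 ± 0.23 in WT (SD, n = 2), 8.66-fold lower (log2 difference -3.12, SE 0.425, adjusted p = 0.00203), and ATHSP22.0 was lower too (-1.75, SE 0.210). Of 4 measured heat shock genes 3 were lower, or 4 adjusted over the list alone (median -1.60, camera adjusted p = 4.69e-05, and adjusted p = 0.079 with an estimated correlation). The peptidyl-prolyl isomerase gene AT5G48570 (-2.60, SE 0.334) and the linker histone gene HIS1-3 (-2.23, SE 0.302) were also lower. SDH2-1 was 4.03-fold higher (2.01, SE 0.16, adjusted p = 0.000123). The TCA cycle had 2 of 8 higher and 0 lower, or 3 and 0 adjusted over the list alone (median 0.35, camera adjusted p = 0.000955, and adjusted p = 0.0746 with an estimated correlation), and 1 higher without either WT dry array or KD dry replicate 2. In the aspartate family 2 of 5 were higher, also adjusted over the list alone (median 0.37, camera adjusted p = 0.000955, and adjusted p = 0.0746 with an estimated correlation), with LKR/SDH (AT4G33150) 14.0-fold higher (3.81, SE 0.267). The other, AT1G14810, measured 1.03 (SE 0.232, adjusted p = 0.0243), with adjusted p = 0.0627 and 0.172 without WT dry replicates 1 and 2, 0.11 and 0.134 without KD dry replicates 1 and 2, and 0.091 without the arrays of conflicting source names. In each of these cases LKR/SDH was the 1 member left.

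In amino acid catabolism 4 of 7 genes passed as higher in dry KD seeds and 0 as lower, also adjusted over the list alone (median 0.67, camera adjusted p = 0.000955, and adjusted p = 0.079 with an estimated correlation). IVD measured 1.35 (SE 0.258, adjusted p = 0.011), with adjusted p = 0.102 without WT dry replicate 2 and 0.0824 without KD dry replicate 1, and 0.0563 without the arrays of conflicting source names. MCCB measured 1.29 (SE 0.275, adjusted p = 0.0189), with adjusted p = 0.0562 and 0.14 without WT dry replicates 1 and 2, and 0.123 and 0.0654 without KD dry replicates 1 and 2. ETFBETA measured 0.94 (SE 0.221, adjusted p = 0.029), with adjusted p = 0.218 without WT dry replicate 2, 0.115 and 0.158 without KD dry replicates 1 and 2 and 0.108 without the arrays of conflicting source names. ETFQO measured 0.67 (SE 0.163, adjusted p = 0.0337), with adjusted p from 0.0908 to 0.186 without any 1 of the dry arrays, 0.127 without those of conflicting source names, 0.054 after quantile normalization and 0.0581 with an eBayes trend. In all, 2 and 0 of the 7 passed without WT dry replicates 1 and 2, 0 and 1 without KD dry replicates 1 and 2, and 1 without the arrays of conflicting source names. LEA genes (1 of 20 higher, camera adjusted p = 0.198) and photosynthesis genes (0 of 10, median 0.005, mean -0.0235, camera adjusted p = 0.776) did not pass as lists. AT5G18470 was 17.3-fold higher in KD (4.11, SE 0.388, adjusted p = 0.000278), DI21, a drought-induced LEA gene, 13.6-fold (3.77, SE 0.306) and the defensin gene PDF1.4 10.5-fold (3.4, SE 0.234). AT1G27030 was 17.8-fold lower (-4.16, SE 0.251). Over all probe sets 912 were higher and 888 lower, and the total of 1800 was 926 and 676 without WT dry replicates 1 and 2, and 873 and 612 without KD dry replicates 1 and 2.

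**Figure D3:**
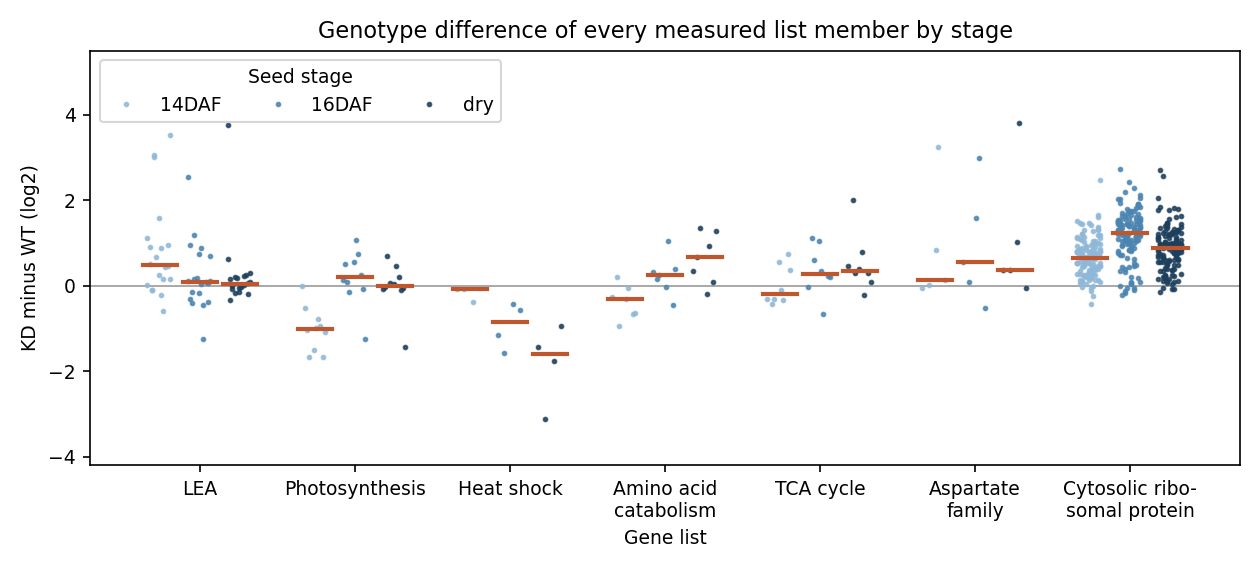
KD minus WT log2 difference (y axis) of every measured member of 7 gene lists (x axis), with 1 point per gene, light to dark blue for 14DAF, 16DAF and dry seeds, and an orange line at each median. The heat shock medians lie at -0.08, -0.86 and -1.60 and the cytosolic ribosomal protein medians at 0.65, 1.24 and 0.90; the ribosomal list was written after the data had been seen.

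Averaged over the 3 stages, AT1G73490 (4.09, SE 0.117, adjusted p = 1.49e-07) and LKR/SDH (AT4G33150; 3.34, SE 0.154, adjusted p = 4.41e-06) differed most among the named genes, at 16.97-fold and 10.2-fold higher in KD. Of the 4590 calls 2089 were unnamed and not ranked. AT1G17960 (3.09, SE 0.224) and AT5G22440 (2.31, SE 0.164) were higher, and AT1G27030 (-2.50, SE 0.145) and AT1G63190 (-2.37, SE 0.0929) lower. All 4 heat shock genes were lower, also adjusted over the list alone (median -0.87, camera adjusted p = 0.00432, and adjusted p = 0.226 with an estimated correlation), and 2 without KD 14DAF replicate 2. The aspartate family had 3 of 5 higher, also adjusted over the list alone, with AT1G14810 at 1.15 (SE 0.134). Its median was 0.29 and its mean, with LKR/SDH in the list, 0.959 (camera adjusted p = 0.00572, and adjusted p = 0.139 with an estimated correlation). The TCA cycle had 4 of 8 higher and 1 lower, also adjusted over the list alone (median 0.28, camera adjusted p = 0.00995, and adjusted p = 0.169 with an estimated correlation). Fewer of its genes were higher when some single arrays were left out. In this list SDH2-1 averaged 0.90 (SE 0.0926), but its direction was not the same at all stages. It was lower in KD at 14DAF, where it did not pass. LEA genes had 4 of 20 higher and 1 lower, or 7 and 1 adjusted over the list alone (median 0.26, camera adjusted p = 0.00995, and adjusted p = 0.466 with an estimated correlation), and 7 higher without WT 16DAF replicate 2. Photosynthesis genes had 0 of 10 higher and 1 lower, or 0 lower adjusted over the list alone (camera adjusted p = 0.501, and 0.0109 without WT 14DAF replicate 1), and amino acid catabolism 2 of 7 higher and 1 lower (camera adjusted p = 0.283). CRT1b was lower (-0.90, SE 0.178), while OLEO3 (-0.25, adjusted p = 0.295), FaTA (-0.12, adjusted p = 0.441), ICL (0.09, adjusted p = 0.598) and AGL62 (0.17, adjusted p = 0.324) did not pass. Storage proteins had 0 of 5 passing, or 1 higher and 1 lower adjusted over the list alone (median -0.04, mean 0.027, camera adjusted p = 0.955). In total 1984 probe sets were higher and 2606 lower in KD (4590 in all). Those higher made up 43.2% of the calls as deposited, 49.2% after quantile normalization and 52.9% with the arrays centred, where the majority direction turned.

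The genotype differences were then compared between stages, in pairs that share no array. They correlated across probe sets at r = 0.481 (rho = 0.400) for 14DAF with 16DAF, 0.282 (0.247) for 14DAF with dry seeds and 0.489 (0.387) for 16DAF with dry seeds; probe sets are not independent replicates. Probe sets higher in KD numbered 433 in common at 14DAF and 16DAF against 39.9 for independent lists, 215 against 30.6 at 14DAF and in dry seeds, and 410 against 47.6 at 16DAF and in dry seeds. Those lower in common numbered 296 against 52.4, 151 against 34.8 and 319 against 52.2. Probe sets called in opposite directions numbered 6 and 13 at 14DAF and 16DAF, against 44.9 and 46.5. They numbered 9 and 28 against 29.8 and 35.7 at 14DAF and in dry seeds. At 16DAF and in dry seeds they numbered 13 and 8 against 46.4 and 53.6. All calls share 1 estimate of the spread, so independent lists are a low baseline, here and for the stage changes. At all 3 stages 187 probe sets were higher and 98 lower in KD. The genotype difference at 14DAF correlated weakly with the change of WT seeds from 16DAF to dry (r = 0.173, rho = 0.134, with r from 0.0406 to 0.248 on single arrays). It correlated more with the WT change from 14DAF to 16DAF, a comparison chosen after the results had been seen. With a different WT 14DAF array on each side, r was 0.328 with replicate 1 in the genotype difference and 0.5 with replicate 2. For the difference at 16DAF and the WT change from 14DAF to dry, r was 0.0661 (rho = 0.0686) and changed sign between single arrays, from -0.152 to 0.280. In dry seeds the correlation with the WT change from 14DAF to 16DAF was -0.0220 (rho = 0.000685), from -0.144 to 0.107 with single arrays.

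Whether the stage changes themselves differed between KD and WT was tested as an interaction. From 14DAF to 16DAF the LEA genes AT3G53040 and AT2G42560 rose less in KD than in WT (interaction -2.83, SE 0.381, adjusted p = 0.0246, and -2.90, SE 0.437, adjusted p = 0.0325). The LEA list differed in the same direction, with 0 of 20 passing upward and 2 downward, or 1 and 3 adjusted over the list alone (median -0.45, camera adjusted p = 0.00446, and adjusted p = 0.388 with an estimated correlation); without WT 16DAF replicate 2 its median was -0.19 (adjusted p = 0.0795). Of the photosynthesis genes 1 of 10 passed as falling less in KD, or 3 adjusted over the list alone (median 1.35, camera adjusted p = 3.33e-05, and adjusted p = 0.317 with an estimated correlation), with SBPASE at 2.06 (SE 0.307, adjusted p = 0.0316). Amino acid catabolism had 0 of 7 passing, or 2 adjusted over the list alone (median 0.59, camera adjusted p = 0.0022, and adjusted p = 0.317 with an estimated correlation). The TCA cycle had 1 of 8 passing upward and 0 downward (median 0.37, camera adjusted p = 0.0545, and adjusted p = 0.317 with an estimated correlation). The gene was SDH2-1 (interaction 1.54), which did not pass from the arrays of this contrast alone (adjusted p = 0.124) or without most single arrays. Heat shock genes had 0 of 4 passing for this step (median -0.79, camera adjusted p = 0.101). Their median was -1.37 without WT 16DAF replicate 1, -1.37 without the arrays of conflicting source names and -1.12 without KD 14DAF replicate 2. Both the size and whether the list passed thus depended on single arrays. From 16DAF to dry seeds PDF1.4 rose more in KD (interaction 3.15, SE 0.330, adjusted p = 0.00383) and AT1G71691 fell more (-3.88, SE 0.460, adjusted p = 0.00523), while heat shock genes had 0 of 4 passing, or 1 lower adjusted over the list alone (camera adjusted p = 0.0601, and 0.000181 without WT 16DAF replicate 2 and 0.0388 without KD 16DAF replicate 1). For the earlier step 81 probe sets passed, 46 up and 35 down, and for the later step 313, 174 up and 139 down. Leaving out WT 14DAF replicates 1 and 2 gave 458 and 3 for the earlier step, WT 16DAF replicates 1 and 2 gave 205 and 12, either WT dry array gave 15, KD 14DAF replicates 1 and 2 gave 6 and 7, KD 16DAF replicates 1 and 2 gave 20 and 9, and either KD dry array gave 14. The calls of AT3G53040, AT2G42560 and SBPASE were lost whichever array was left out, other than WT 14DAF replicate 1 or WT 16DAF replicate 1, with adjusted p-values from 0.0557 to 0.127, and with only the arrays of the contrast (0.124 to 0.128). So 0 photosynthesis and 0 LEA genes passed without any 1 of these 10 arrays; without the other 2 in turn, 6 and 2 photosynthesis genes and 2 and 4 LEA genes did. For the later step the count was 98 and 110 without WT dry replicates 1 and 2, 99 and 106 without KD 16DAF replicates 1 and 2, and 86 and 72 without KD dry replicates 1 and 2.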

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

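In this part, the added gene lists and the tests of other tissues and of older seeds were chosen after the results had been seen. The results below stand out because the stage change differed between KD and WT by an interaction test. From 14DAF to 16DAF 81 probe sets differed in this way and from 16DAF to dry seeds 313 did. Leaving out single arrays gave 3 (without WT 14DAF replicate 2) to 458 (without WT 14DAF replicate 1) for the earlier step and 72 (without KD dry replicate 2) to 425 (without WT 16DAF replicate 2) for the later one, so the genes below rest on few arrays. With the replicate number as a block the earlier step lost ALDH11A3, TROL, AT1G30515, SBPASE, scpl26, AT5G01090, AT2G41650, FLDH, AT2G42560, AT1G19540 and AT2G47550 (adjusted p from 0.0523 to 0.0917). The later step lost psbJ (0.0618). With only the arrays of the contrast AT2G39210 was the 1 gene of the earlier step to pass, and of the later step AT1G72060, XTH16 and AT1G55450 were lost (0.0625 to 0.0675). Without the arrays of conflicting source names the earlier step lost ALDH11A3 (0.0563) and AT2G41650 (0.0553), and the later step, beside these 3, AT4G31000, AT5G19730, AUR2, AT1G72500 and psbJ, with adjusted p-values from 0.0528 to 0.181 for these 8 genes.

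For the earlier step, the interaction (KD change minus WT change, log2) was positive for the lipase gene AT1G71691 (3.49), ALDH11A3 (2.12), the thylakoid gene TROL (2.12), AT1G30515 (2.07), SBPASE (2.06), scpl26 (1.93), AT5G01090 (1.69), AT2G41650 (1.66), AT1G74790 (1.62) and FLDH (1.57), with adjusted p-values from 0.0201 to 0.0484. It was negative for AT1G27030 (-3.26), AT2G43580 (-3.25), AT2G39210 (-3.17), the LEA genes AT2G42560 (-2.90) and AT3G53040 (-2.83), AT5G42290 (-2.68), AT5G22550 (-2.23), AT1G19540 (-2.01), AT5G44380 (-1.78) and AT2G47550 (-1.67), with adjusted p-values from 0.00271 to 0.0455. For the later step it was positive for the defensin gene PDF1.4 (3.15), AT1G72060 (2.50), the cell wall genes XTH16 (2.43) and EXGT-A3 (2.11), AT1G22890 (2.38), the Hsc70 gene AT3G09440 (2.37), AT1G55450 (2.33), AT2G21630 (2.3), AT2G39210 (2.1) and AT4G31000 (2.09), with adjusted p-values from 0.00204 to 0.0425. Negative values were those of AT1G71691 (-3.88), the S-adenosylmethionine decarboxylase gene AT5G15950 (-3.36), the MYB-family gene AT1G68670 (-2.84), AT5G19730 (-2.68), the Aurora kinase gene AUR2 (-2.54), scpl26 (-2.32), AT5G14500 (-2.31), AT4G23493 (-2.25), AT1G72500 (-2.16) and the plastid gene psbJ (-2.13), with adjusted p-values from 0.00192 to 0.0353.

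Among the lists, the earlier step differed between genotypes for LEA genes (median interaction -0.45, camera adjusted p = 0.00446, and adjusted p = 0.388 with an estimated correlation; -0.19 and 0.0795 without WT 16DAF replicate 2), photosynthesis (1.35, 3.33e-05, and adjusted p = 0.317 with an estimated correlation) and amino acid catabolism (0.59, 0.0022, and adjusted p = 0.317 with an estimated correlation). Of the added lists, the cytosolic ribosomal proteins (0.56, 9.52e-20, and adjusted p = 0.273 with an estimated correlation), the mitochondrial genome (-0.44, 0.00497, and adjusted p = 0.273 with an estimated correlation), the plastid genome (0.13, 0.0284, and adjusted p = 0.466 with an estimated correlation) and ribosome biogenesis (-0.14, 0.00402, and adjusted p = 0.465 with an estimated correlation) differed. In the later step the ribosomal proteins (-0.27, 9.19e-06, and adjusted p = 0.595 with an estimated correlation), the plastid genome (-0.48, 4.79e-11, and adjusted p = 0.351 with an estimated correlation) and ribosome biogenesis (-0.51, 2.06e-09, and adjusted p = 0.351 with an estimated correlation) differed. With fry, which tests whether the genes of a list move on balance one way, none of these 10 interaction calls passed. Without the arrays of conflicting source names the plastid genome in the earlier step (0.179) and the ribosomal proteins in the later one (0.124) did not pass, nor did the former after quantile normalization (0.20).

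The interaction in LEA and photosynthesis genes goes with a difference at 14DAF, where 3 of 20 LEA genes passed as higher and 2 of 10 photosynthesis genes as lower in KD (medians 0.49 and -1.01, the latter -0.24 without WT 14DAF replicate 2; camera adjusted p = 0.000397 for each, and adjusted p = 0.333 with an estimated correlation). RNA quality is argued against as its whole cause: the slope of the LEA minus photosynthesis score on the 3' minus 5' signal between replicates predicted a difference of -0.013 (SE 0.14), against 1.85 observed. More silique wall, funiculus or seed coat in the WT samples cannot be told apart from a genotype effect, since the 5 markers had a median difference of -0.04 but 2 of them lay under log2 5 in both groups. For KD seeds older than WT seeds by an equal amount for all genes, the difference at 14DAF was set against the WT change to 16DAF with a different WT 14DAF array on each side, which gave 0.33 of 1.15 and 0.73 of 0.96 for LEA genes and -0.24 of -2.91 and -1.82 of -1.67 for photosynthesis genes, so the share rests on which array is used. The plastid genome goes against an equal shift: its median difference was -0.025, where the LEA share over all arrays predicts -0.32. That share has the same WT 14DAF arrays on both sides. The bounds set for the plastid test were not met either way, so by them it could not tell. Its single-array medians ran from -0.12 to -0.08 (SD 0.0171). The SD of 0.324 between its 69 genes, 37 of them below 0, is not the error of that median. But with WT 14DAF replicate 1 in the genotype difference, the plastid share (0.0921) was near the photosynthesis share (0.0825). With replicate 2 they were 0.0476 and 1.09. Ribosomal proteins (0.78 and 0.58 against -0.35 and -0.06) moved against the WT change, so an equal shift is not the only difference. Ribosome biogenesis (1.27 and 1.25 against 0.89 and 0.94) moved with it. Both lists were higher in KD at each stage, so they do not test a shift in LEA and photosynthesis genes. For these genes older KD seeds are not excluded and may be the source. A genotype effect on the pace of maturation may be as well and stays a hypothesis.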

How the results depend on the processing

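Centring and quantile normalization of the list tests, and the added lists, were chosen after the data had been seen; the other alternatives were planned. No named gene or list call reversed (0 reversed). Of 280 named gene values past the threshold, 221 passed whichever array was left out, and so did 22 of the 29 calls of the fixed lists; 0 of the 29 held with an estimated correlation. The fixed list calls numbered 29 with all probe sets kept and with the replicate block, 31 without the arrays of conflicting source names, 34 with centred arrays and 30 after quantile normalization, with 1 call lost without those arrays and 1 after quantile normalization. With fry, which tests whether the genes of a list move on balance one way and does not compare them with other genes, 29 passed, 7 gained and 7 lost. Lost were photosynthesis at 14DAF (adjusted p = 0.139) and for the earlier KD step (0.234), amino acid catabolism at 14DAF (0.103), heat shock at 16DAF (0.113), and the interactions of LEA genes (0.164), photosynthesis (0.164) and amino acid catabolism (0.0918). Gained were the aspartate family, seed coat markers and storage proteins on drying in both genotypes, and amino acid catabolism on drying in WT (adjusted p from 0.00437 to 0.0325). Of the calls of the added lists 12 were lost with fry, 2 without the arrays of conflicting source names and 1 each with centred arrays and quantile normalization. The number of list members past the threshold moved by over 1.5 times without some array in 38 of the 53 fixed list tests that had any. Named gene calls lost numbered 2 with centred arrays, 4 with quantile normalization, 0 among probe sets above log2 5 on at least 2 arrays (13427 probe sets), 2 with an eBayes trend, 1 with robust eBayes, 5 with array weights, 36 with only the arrays of a contrast and 20 without the arrays of conflicting source names. No detection calls were used, so how far dim probe sets lie above the background is unknown; between 48.9% and 52.9% of the probe sets of an array lay above log2 5.

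With a minimum change of 2-fold, which only removes calls, 2120 and 4599 probe sets passed for the WT steps from 14DAF to 16DAF and to dry seeds, 909 and 4350 for the KD steps, and 737, 1071, 785 and 496 for KD against WT at 14DAF, at 16DAF, in dry seeds and averaged. With only the arrays of the contrast, which leaves fewer degrees of freedom, 2010 passed for the earlier WT step, 936 and 869 for KD against WT at 14DAF and 16DAF, and 1 and 176 for the interactions of the earlier and later step. The earlier interaction gave 53 with an eBayes trend and 37 with array weights, and the later one 69 without the arrays of conflicting source names; the cause was not tested. Leaving out each array gave 2219 to 4413 for the earlier WT step, 430 to 2789 for the earlier KD step, 441 to 2111, 1019 to 2467 and 612 to 2255 for KD against WT at 14DAF, at 16DAF and in dry seeds, and 3 to 458 and 72 to 425 for the interactions.

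With the replicate number as a block, 22 and 164 probe sets passed for the interactions, and 14 named gene calls were lost. Replicate numbers did not pair the samples throughout: deviations from the group means correlated above 0.1 in 3 of 15 pairs of groups, with a range from -0.33 to 0.417. The 3 pairs were WT 16DAF with KD 16DAF (0.417), WT 14DAF with KD 16DAF (0.277) and WT dry with KD dry (0.17). For WT 14DAF with KD 14DAF the value was -0.212. A pairing of the genotypes by number at 16DAF and in dry seeds is thus not excluded. In other pairs the deviations were related with the numbers swapped, as for WT 14DAF with WT dry (-0.313) and WT 16DAF with KD dry (-0.33). So deviations in different groups were not independent, and the cause was not tested.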

Other observations

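The 4 added gene lists, and their rerun without the loci seen before they were written, were chosen after the results had been seen; the tests on them below were planned before their values were computed. Genes of cytosolic ribosomal proteins were higher in KD at each stage. Of 127 measured, 51 were higher at 14DAF, 106 at 16DAF and 78 in dry seeds, with 0 lower at each, or 85, 110 and 97 adjusted over the list alone. The medians were 0.65, 1.24 and 0.90, with camera adjusted p-values of 6.11e-31, 4.83e-62 and 9.95e-51, and adjusted p = 0.213, 0.0738 and 0.0746 with an estimated correlation. AT5G22440 at 16DAF was among the largest (2.75, SE 0.284). In WT 2 of 127 rose and 34 fell from 16DAF to the dry state, or 2 and 31 adjusted over the list alone (median -0.27, camera adjusted p = 0.000181, and adjusted p = 0.483 with an estimated correlation), and in KD 61 fell and 0 rose, or 62 and 0 adjusted over the list alone (median -0.54, 1.71e-12, and adjusted p = 0.387 with an estimated correlation). From 14DAF to 16DAF 3 rose and 17 fell in WT, or 3 and 14 adjusted over the list alone (median -0.20, camera adjusted p = 4.17e-05, and adjusted p = 0.467 with an estimated correlation). In KD 5 rose and 0 fell, and 0 passed adjusted over the list alone (median 0.25, camera adjusted p = 2.71e-08, and adjusted p = 0.452 with an estimated correlation). With fry, which tests whether a list's genes move on balance one way, the ribosomal protein calls of the stage steps were lost other than that of drying KD seeds (adjusted p = 0.225 and 0.0682 for the WT steps and 0.187 for the earlier KD step). Without the loci seen beforehand, 123 members had medians of 0.64, 1.23 and 0.89 for KD against WT.

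Ribosome biogenesis genes, which act in the nucleolus to assemble the subunits, were higher in KD for 24, 20 and 8 of 31 at 14DAF, 16DAF and in dry seeds, with 0 lower, or 28, 26 and 9 adjusted over the list alone. Their medians were 1.32, 0.92 and 0.38 (camera adjusted p = 8.96e-30, 1.2e-20 and 1.52e-07, and adjusted p = 0.0628, 0.0738 and 0.149 with an estimated correlation). They also rose from 14DAF to 16DAF, 22 of 31 in WT (median 0.96, 2.73e-14, and adjusted p = 0.107 with an estimated correlation) and 10 in KD (0.61, 1.54e-12, and adjusted p = 0.208 with an estimated correlation). Genes of the plastid genome fell over the same step, 37 of 69 in WT (median -0.76, 2.21e-16, and adjusted p = 0.107 with an estimated correlation) and 22 in KD (-0.61, 1.29e-16, and adjusted p = 0.208 with an estimated correlation). In dry seeds 19 were lower in KD than in WT with 0 higher (-0.46, 1.27e-10, and adjusted p = 0.109 with an estimated correlation). On drying, 28 plastid genes rose and 10 fell in WT (median 0.515, camera adjusted p = 0.0141, and 0.483 with an estimated correlation). In KD 12 rose and 15 fell (0.02, 0.346). Ribosome biogenesis had 18 of 31 rising and 0 falling on drying in WT (median 0.645, camera adjusted p = 0.000128, and 0.395 with an estimated correlation). In KD 2 rose and 2 fell (0.125, 0.664). Genes of the mitochondrial genome rose on drying, 8 of 11 with 1 falling in WT (median 1.20, 0.00563, and adjusted p = 0.395 with an estimated correlation) and 8 with 0 falling in KD (1.39, 0.000601, and adjusted p = 0.387 with an estimated correlation). The 3' minus 5' signal fell on drying too, from 2.95 to 2.19 in WT and from 2.41 to 2.21 in KD.

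The higher ribosomal protein transcripts of KD were weighed against technical explanations. A scaling that depends on the signal level is argued against, since the highest median of 10000 random lists matched on mean signal was 0.0883, against 0.953 for the list averaged over stages. RNA quality is argued against as well: the slope of the score on the 3' minus 5' signal between replicates predicted -0.0319 (SE 0.0378) of an observed score difference of 0.911. Cross-hybridisation between paralogs cannot be told apart, because all 127 members lie on probe sets not marked as shared, so their median of 0.953 has nothing to be set against. A genotype effect on ribosomal protein transcripts may be the source and stays a hypothesis.

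Whether genes that differ between KD and WT at all 3 stages lie in a few chromosome segments, as they would if a line carried segments of another accession, was tested on 13264 placed genes, with gene order taken from the TAIR10.1 table. Of these, 166 (1.25%) differed at each stage, 115 higher and 51 lower in KD. The highest number in a window of 100 neighbouring measured genes was 5, below the median of 6 over 10000 random placements, so no such segments were seen. As many genes changing from 14DAF to 16DAF in WT reached 7 in a window, the 95th percentile of the random placements (7).

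The number of probe sets that differed between KD and WT averaged over stages, 4590, was set against other splits of the arrays within stages. Of 100 splits drawn from 108 possible, 1, the real one, gave as many; the highest other split gave 1286 and the median of the others was 0. Splits that separate the arrays of a group put any genotype difference into the spread, so low counts follow from their design. Counts from such splits cannot decide whether the real count arose by chance. A chance difference between single batches of plants is not excluded either, since the repeats are not shown to be separate plants or harvests.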
